A study of Mus musculus with 5 samples.

How the data were processed

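Single-cell RNA sequencing was carried out on lung epithelial cells of Scgb1a1-CreERTM;Rosa-tdTomato mice. Tamoxifen turns on the red fluorescent protein tdTomato in their cells that express Scgb1a1, the main secretory protein of airway club cells. Per the labels' protocols, mice of both sexes aged 8 to 10 weeks received 3 doses of tamoxifen (200 mg/kg) 2 days apart and, 1 week later, a single oropharyngeal dose of porcine pancreatic elastase (PPE, 40 U/kg in 80 µl), which digests elastin and produces emphysema-like airspace enlargement, or saline. Lungs were taken at day 21. Dispase-digested lung was passed through 70 µm and 40 µm strainers, enriched on an Epcam column and sorted for live cells positive for Epcam and tdTomato, so shares of cell types describe the sorted cells and not the lung. Libraries were made with the 10x Chromium 3' chemistry.

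The authors deposited 1 matrix of raw UMI counts for all cells, which holds whole numbers of at least 1 per gene and cell, together with a table that gives each cell's library and cell class. Per the submitters' processing notes the tools were Cell Ranger and Seurat and the genome build was mm10. Versions, the filters on cells and genes, and the removal of doublets are not given in the sources used here. The matrix held 13443 cells and 17258 genes, given by symbol alone. The deposited cell class and the 2 deposited coordinates of an embedding, which carry the unit score, have column names that refer to harmony, a batch integration method, per the file headers. The coordinates were not used. Every cell's library name matched 1 sample title, and the treatment came from the labels.

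There were 3 PPE and 2 saline libraries in 2 experiments. Experiment 1 held 1 library of each treatment, and experiment 2 held 2 PPE libraries and 1 saline library. The labels do not tie libraries to single mice, and both libraries of experiment 1 held cells with Xist alone and cells with Y-linked transcripts alone. The p-values of single genes and of shares therefore measure the spread between libraries, and those of gene lists are described below. Counts of 2 libraries were compared by chi-square: the statistic per degree of freedom was 15.9 for the PPE pair of experiment 2 and between 134.3 and 153 for the other same-treatment pairs, so no library was a copy of another of its treatment. Libraries of different treatments were not compared in this way. The sample titles share experiment numbers between treatments. In AT2 cells, deviations from the group mean correlated within experiments (0.62, 0.32 and 0.49) and were negative across them (−0.62 to −0.32); with 2 saline libraries these values come in mirrored pairs. The first principal component, with 57.7% of the variance, separated the experiments. The experiment number was therefore read as a shared batch.

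Cell classes were the authors'. AT2 cells were the 6 deposited AT2 substates (9547 cells), airway secretory cells were Club, Goblet and Other Activated Club Cells (1540 cells), and ciliated cells were 1807 cells. Markers fixed before the data were examined were looked for among the 10 genes with the highest fold in each class. The fixed markers held no dendritic cell set, so the class named DC was bound to show 0 of its own. It had 1 of another class there, and only its share of cells was compared. Goblet had 7 of its own and 2 of others. No filter on cells was added. Scrublet (in scanpy 1.11.5, expected rate 0.06) marked 28 of 13443 cells (0.208%) as doublets at its automatic threshold, which at this number of cells is read as a caller that did not work. An alternative left out the 1041 cells with the highest scores.

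UMI counts were summed per library and class, with at least 20 cells required. PPE and saline sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, R 4.3.3) with treatment as the only term and Benjamini-Hochberg adjustment at 0.05. The same fit with experiment as a term is printed wherever it changed a call or moved a count by more than 1.5 times. Levels are TMM-scaled CPM, given as mean ± SD over 3 PPE and 2 saline libraries; log2 changes are PPE minus saline with their SE. The difference of the PPE effect between AT2 and secretory cells was an interaction in edgeR with the library as a block. Shares of cells were compared by exact two-sided permutation tests over the 10 arrangements, whose smallest possible p is 0.1. Confidence intervals are exact binomial at 95% and, like the limit of 3 counts behind a 0, cover counting error only.

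Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, voom) wherever at least 5 members were tested. This preset takes the genes of a list as nearly independent, so camera's small p-values depend on the number of genes. They do not measure the spread between libraries alone. The lists were AT2 identity, AT1, club, goblet, ciliated, basal, hillock, neuroendocrine, tuft and ionocyte, proliferation, macrophage, neutrophil, lymphocyte, endothelial, fibroblast, mesothelial and erythroid markers; MHC class I, MHC class II, NF-kB and chemokines, interferon response, primed AT2 and acute phase, transitional alveolar epithelium, cholesterol synthesis, surfactant lipid synthesis, oxidative phosphorylation, unfolded protein response, p53 and senescence, Notch, Wnt, YAP, TGF-beta and BMP, extracellular matrix, and antioxidant genes; and dissociation stress, mitochondrial and sex genes. Estimated correlation and fry were alternatives; fry asks whether a list's genes move one way on balance and does not compare them with other genes. No list call of PPE against saline, and none of the difference between classes, held with an estimated correlation or in fry. Both also missed single lists shifted on purpose in simulated counts of AT2 and secretory cells, which the preset called. Their lowest adjusted p for a shifted list was 0.203 with an estimated correlation and 0.0695 in fry. A call lost in them therefore cannot decide whether a list shifted between PPE and saline. Genes were drawn independently in that simulation, so it does not test the preset correlation. Even so, the preset also called lists that were not shifted. In secretory cells with treatment alone it called 2 beside MHC class II and 1 beside interferon response. In AT2 cells with experiment as a term it called 1 beside interferon response. Fry called 1 such list beside interferon response in secretory cells with experiment as a term.

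The lists, tests, other settings and the rule for named genes were fixed before the data were examined. The rule takes up to 8 genes per direction that pass, reach 20 CPM in a group and change the same way in both experiments; where none pass, the 4 with the smallest p per direction, said not to pass; up to 4 members with the smallest p of each list that passes; and always Sftpc, Scgb1a1, Scgb3a2, Lyz2, Krt8, Ager, Foxj1, Cdkn1a, Lcn2 and Axin2. The substate and interaction genes, and genes outside these, were chosen after their values were seen. The list test in ciliated cells and the list test of the difference between classes were added after the data were seen.

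For the share of cells with an airway transcript each cell was thinned to 2000 UMIs and shallower cells were left out. The other settings fixed beforehand were the experiment term, experiment and replicate number as a term, DESeq2 1.42.0 and its size factors, no low-count filter, each library left out in turn, cells with at least 1000 UMIs and under 10% mitochondrial counts, Scrublet calls and equal cell numbers.

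The tests were run on simulated counts, with 100 genes changed by 2-fold and 100 by 4-fold. With treatment alone edgeR recovered 32% and 93% of them in AT2 cells, 0% and 33% in secretory cells, and 1% and 79% in ciliated cells. With experiment as a term it recovered 96% to 100% of them, and false calls made up 4.33% of the calls in AT2 cells, 9.13% in secretory cells and 10.5% in ciliated cells. The interaction recovered 57% and 100%, with 4.27% false calls. For PPE against saline the simulated means were those of each experiment, and the spread was estimated with experiment as a term. The fit with that term therefore matched the simulation by construction. Its lead over treatment alone cannot decide which fit suits the measured data. These shares describe the simulated genes and were not split by expression level, so they need not hold for genes with few counts. Measured genes can also fall short of them. In AT2 cells Lcn2 did not pass with experiment as a term, at a log2 change of 1.36, which is more than 2-fold. Gene coordinates are from GENCODE M21 on GRCm38, the assembly of mm10; all 270 symbols looked up were found.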

Results

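The libraries profiled lineage-traced lung epithelium 21 days after elastase or saline, to ask how alveolar type II (AT2) cells, which make surfactant and renew the alveolar lining, and airway cells differ in emphysema. The 13443 cells comprised 7975 from PPE and 5468 from saline libraries. The PPE library of experiment 1 held 2300 cells and 45585656 UMIs, and its saline partner 1853 cells and 28741475 UMIs. In experiment 2, PPE replicate 1 held 2762 cells and 17472322 UMIs, PPE replicate 2 held 2913 cells and 14061216 UMIs, and the saline library held 3615 cells and 23413032 UMIs. Median depth was 17578.5 and 13561 UMIs per cell in experiment 1 and 5747, 4298 and 5767 in experiment 2, so experiment 1 held more UMIs per cell.

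In AT2 cells, 4 genes were higher after PPE and 2 were lower once experiment was a term of the model. Cd14, a co-receptor for bacterial lipopolysaccharide, stood at 69.2 ± 7.33 CPM in PPE libraries (SD, n = 3) and 24.2 ± 7.26 CPM in saline libraries (n = 2). Cxcl2, a neutrophil-attracting chemokine, stood at 15.3 ± 4.97 against 4.14 ± 1.84 CPM and Steap4, a metalloreductase, at 19.6 ± 5.64 against 5.48 ± 0.202 CPM. Il4i1, an amino acid oxidase, stood at 4.84 ± 1.76 against 0.403 ± 0.0218 CPM. Cyp2b10, a xenobiotic-metabolising cytochrome P450, was at 115 ± 14.1 against 195 ± 12.7 CPM, and Thbs1, a matrix glycoprotein, at 30.9 ± 0.444 against 66.7 ± 19.2 CPM. These 6 genes passed with experiment as a term, but without AT2 (6) cells, a fit chosen after seeing the data, Thbs1 alone passed (−1.06, adjusted p = 0.0310). In that fit Cd14 was at 0.78 ± 0.11, Cxcl2 at 0.95 ± 0.58, Steap4 at 0.57 ± 0.20 and Cyp2b10 at −0.74 ± 0.10, and Il4i1 had too few counts to be tested. Cd14, Cxcl2 and Steap4 are among the genes that lead AT2 (6), whose cells were commoner in PPE libraries. Leaving those cells out was therefore bound to lower these 3 changes, whatever their cause. With all AT2 cells the edgeR log2 changes were 1.59 ± 0.12 for Cd14 (adjusted p = 0.00701), 2.03 ± 0.17 for Cxcl2 (adjusted p = 0.00894), 3.34 for Il4i1, 1.69 for Steap4, −1.12 for Thbs1 and −0.80 for Cyp2b10 (adjusted p = 0.0330 for each of the last 4). None of the 6 passed when experiment 1 was split by sex of cells with experiment and sex as terms, a fit chosen after seeing the data. With treatment alone edgeR called 0 of 12084 genes (248 at an unadjusted p under 0.05). DESeq2 called 16, among them Cd14 (adjusted p = 8.78e-06), Il4i1 (8.78e-06), Steap4 (5.82e-05), Cxcl2 (0.00238), Thbs1 (0.00323) and Cyp2b10 (0.0491). Without the PPE library of experiment 1 the treatment-only fit called 4 genes, all higher: Pigr, Ly6i, Steap4 and Il4i1, of which Pigr and Ly6i are named after their values were seen.

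**Figure D1:**
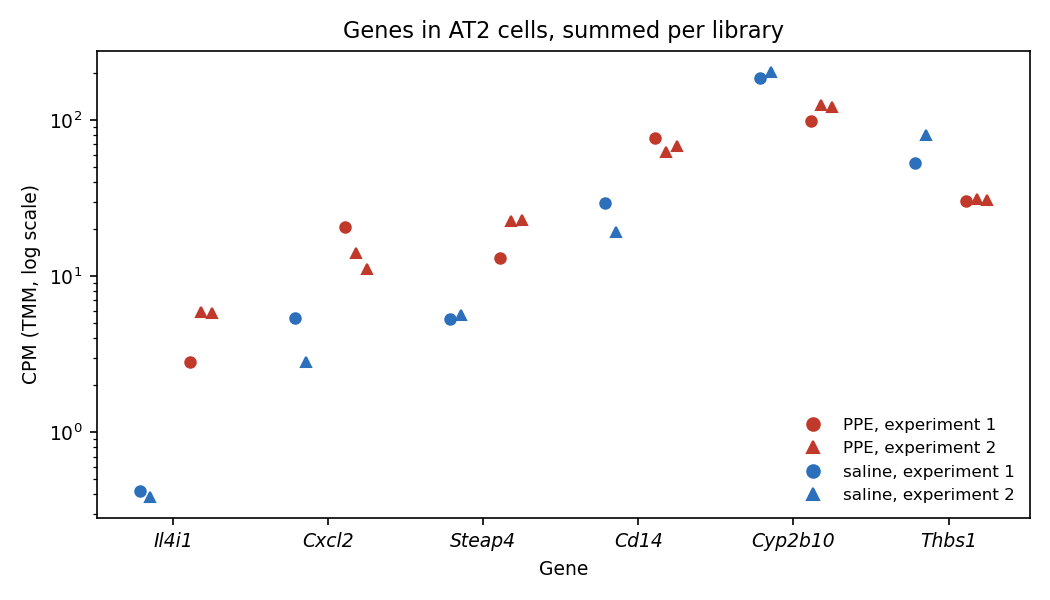
TMM-scaled CPM (log axis) in AT2 cells for the 6 genes that passed in edgeR with experiment as a term; each point is a library, red for PPE and blue for saline, circles for experiment 1 and triangles for experiment 2. Il4i1, Cxcl2, Steap4 and Cd14 lie higher and Cyp2b10 and Thbs1 lower in all 3 PPE libraries than in both saline libraries, although 0 genes passed with treatment alone. Without AT2 (6) cells Thbs1 alone passed with experiment as a term, but Cd14, Cxcl2 and Steap4 are among the genes that lead AT2 (6).

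The same 6 loci on mm10 are Cd14 on chromosome 18 from 36725067 to 36726798, Cxcl2 on chromosome 5 from 90903871 to 90905938, and Steap4 on chromosome 5 from 7960457 to 7982213. Il4i1 lies on chromosome 7 from 44816387 to 44840809, Cyp2b10 on chromosome 7 from 25897620 to 25926624, and Thbs1 on chromosome 2 from 118111876 to 118127133. The other genes with the smallest p did not pass in either edgeR fit. They were Fcer2a, a low-affinity IgE receptor that DESeq2 called (adjusted p = 8.78e-06), at log2 2.40 ± 0.38, Cblb, a ubiquitin ligase, at −0.81 ± 0.15, and Prmt8, an arginine methyltransferase, at −0.61 ± 0.12. Surfactant protein C (Sftpc, −0.24 ± 0.62), Scgb1a1 (0.31 ± 0.44), Scgb3a2 (0.25 ± 0.37), lysozyme Lyz2 (−0.01 ± 0.39), keratin Krt8 (−0.42 ± 0.24), the AT1 marker Ager (−0.08), Foxj1 (0.06), Cdkn1a (−0.11) and Axin2 (−0.11) did not pass either. Lcn2, an iron-binding acute phase protein, averaged 2352 ± 73.9 against 1006 ± 470 CPM and did not pass (log2 1.23 ± 0.34; edgeR adjusted p = 0.143 with experiment as a term). DESeq2 called it (adjusted p = 0.0251).

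In AT2 cells of PPE libraries immune and acute phase lists were higher. Camera called the 4 lists below, and the calls were lost with an estimated correlation, at an adjusted p of 0.134 for MHC class I, NF-kB and primed AT2 genes and 0.251 for interferon response. MHC class I genes, which present antigen, rose: 16 of 16 members were higher, with a median log2 change of 0.42, led by H2-Q7 (1.43 ± 0.27; 55.1 against 20.4 CPM), H2-Q6 (1.07), H2-Q4 (0.86) and the immunoproteasome subunit Psmb8 (0.66). NF-kB targets and chemokines rose in 17 of 20 members (median 0.49), led by Tnfaip3 (0.77), Cxcl2 (1.89), Cxcl3 (1.63) and Cx3cl1 (1.38). Primed AT2 and acute phase genes rose in 14 of 17 (median 0.71), led by Lrg1 (0.98 ± 0.21; 601 against 304 CPM), the anion exchanger Slc26a4 (1.44), Lcn2 and Orm2 (2.94). Interferon response genes rose in 17 of 18 (median 0.46), led by Isg15 (1.31), Gbp2 (1.26), Parp14 (0.44) and Zbp1 (1.21). In edgeR the single members named here did not pass over all genes, apart from Cxcl2 with experiment as a term. DESeq2 called H2-Q7 (adjusted p = 0.00167), Lrg1 (0.00167), Cxcl2, Slc26a4 (0.0182), Cxcl3 (0.0251) and Lcn2 (0.0251). H2-Q7, H2-Q6 and H2-Q4 are near-identical paralogs whose reads can be split between them, so their single values are uncertain.

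Camera gave these lists adjusted p-values of 1.21e-15 (MHC class I), 2.09e-14 (NF-kB and chemokines), 4.28e-14 (primed AT2 and acute phase) and 1.81e-12 (interferon response). Adjusted over the list alone, 4, 7, 3 and 1 members passed, and 14, 12, 14 and 9 with experiment as a term. Over all genes tested 0 members of each passed in edgeR, and with experiment as a term Cxcl2 alone. The median changes were positive in experiment 1 (0.37, 0.46, 0.76 and 0.43) and in experiment 2 (0.54, 0.65, 0.50 and 0.57).

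Smaller shifts passed for 3 other lists in AT2 cells. Cholesterol synthesis genes rose in 22 of 24 members (median 0.13), among them Tm7sf2 (0.35), Mvd (0.38) and Lss (0.21), while Pmvk, a phosphomevalonate kinase, went the other way at −1.15. MHC class II genes rose in 7 of 9 (median 0.14; H2-Eb2 1.34, H2-DMb2 1.17, Ciita 0.50 and H2-Ab1 0.19). Without the saline library of experiment 1 H2-DMb2 was at 1.83 and Ciita at 0.93, without that of experiment 2 at 0.73 and 0.18, and H2-Ab1 was at 0.0764 without the PPE library of experiment 1. AT1 markers fell in 16 of 20 (median −0.13), with Cav1 at −0.91, Lmo7 at −0.57 and Col4a3 at −0.56 against Pdpn at 0.86. Camera's adjusted p was 0.0251 for cholesterol synthesis and 0.0322 for the other pair; with an estimated correlation the adjusted p was 0.768 for all 3. Adjusted over the list alone, 0, 0 and 1 members passed. Cholesterol synthesis was lost without the PPE library of experiment 1 (0.119), PPE replicate 1 of experiment 2 (0.832) or the saline library of experiment 2 (0.815), and without a low-count filter (0.138). MHC class II was lost without the PPE library of experiment 1 (0.718) or the saline library of experiment 2 (0.684), without the filter (0.105), and without AT2 (6) cells (0.221). AT1 was lost without PPE replicate 1 (0.146), PPE replicate 2 (0.0614) or the saline library of experiment 2 (0.684). Its medians were 0.02 in experiment 1 and −0.26 in experiment 2, against −0.03 and 0.23 for cholesterol synthesis.

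Of 27 lists tested in AT2 cells the remaining 20 did not pass in camera. Dissociation stress, a sign of tissue handling, and transitional alveolar epithelium were lower at adjusted p = 0.0581 each. The others were ciliated (0.105), mitochondrial (0.166), p53 and senescence (0.234), YAP (0.375), surfactant lipid synthesis (0.557), antioxidant (0.566), proliferation (0.585), Notch (0.612), goblet, AT2 identity and macrophage (0.615 each). At higher values stood Wnt and extracellular matrix (0.659 each), unfolded protein response and TGF-beta (0.807 each), club (0.814) and sex genes (0.858). Oxidative phosphorylation had a median of −0.04 (0.659) with treatment alone and rose with experiment as a term (adjusted p = 0.000978), where its adjusted p with an estimated correlation was 0.703. It also passed upward without the saline library of experiment 1 (3.00e-07; 44 members higher). It passed downward without the PPE library of experiment 1 (0.00160; 37 lower) or the saline library of experiment 2 (1.60e-07; 41 lower). For antioxidant, Notch and goblet genes the median, the mean and the test did not share 1 sign. Under 5 members were tested of 10 lists, which have no result in AT2 cells: basal, hillock, neuroendocrine, tuft and ionocyte, neutrophil, lymphocyte, endothelial, fibroblast, mesothelial and erythroid.

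**Figure D2:**
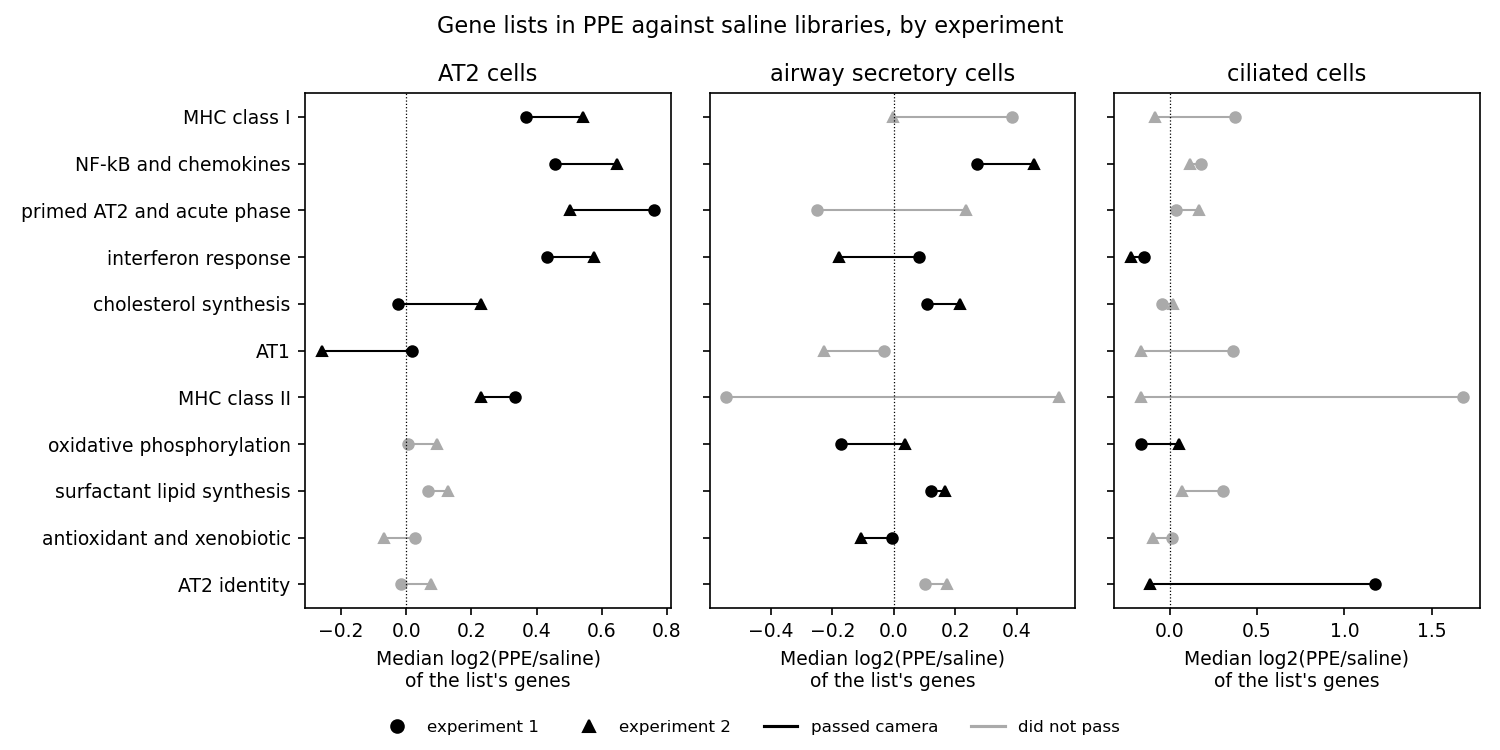
Median log2 difference between PPE and saline libraries of each list's genes within experiment 1 (circles) and experiment 2 (triangles), in 3 cell groups with separate horizontal scales; black lists passed camera with treatment alone and grey lists did not. In AT2 cells the 4 lists at the top lie to the right of 0 in both experiments, with MHC class I at 0.37 and 0.54.

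Among the 6 deposited AT2 substates, AT2 (6) made up a larger share of AT2 cells in each PPE library. It held 9.50% of AT2 cells in the PPE library and 3.27% in the saline library of experiment 1, and 15.9% and 13.7% in the PPE libraries against 0.822% in the saline library of experiment 2. The means were 13.0 ± 3.25% (SD, n = 3) and 2.05 ± 1.73% (n = 2), and the exact permutation p was 0.1, the smallest this design allows (adjusted p = 0.2). edgeR on cell counts gave an adjusted p of 0.105, and with experiment as a term a log2 change of 2.82 ± 0.65 (adjusted p = 0.00586), a 7.08-fold difference. The 10 genes that lead AT2 (6), Ly6i, Lcn2, Slc26a4, Cxcl1, Cxcl5, Slpi, Cxcl2, Cd14, Vnn1 and Steap4, were also higher in PPE cells outside it, by 0.26 to 1.76 on the log2 scale. With experiment as a term edgeR called 0 of them there (lowest adjusted p = 0.172). AT2 (6) held 161, 293 and 277 cells in the PPE libraries and 51 and 20 in the saline libraries. The choice of its leading genes can thus favour genes higher in PPE cells, so their rise outside it is not independent evidence. Without the experiment 2 cells of the other sex, left out after seeing the data, the saline share of experiment 2 was 0.495% and the blocked fold 8.84 (adjusted p = 0.0275).

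No other substate passed. AT2 (5) made up 8.56 ± 2.12% of AT2 cells in PPE and 17.4 ± 7.21% in saline libraries, and AT2 (2) 24.3 ± 2.12% and 31.7 ± 2.59%. The exact p was 0.1 for both, and with experiment as a term the adjusted p was 0.153 and 0.475. AT2 (5) differed by −1.82 points in experiment 1 and −14.9 points in experiment 2, and by −14.0 points without the saline library of experiment 1 and −3.76 points without that of experiment 2. AT2 (1) was at 33.1 ± 7.57% and 34.8 ± 12.3% (exact p = 0.9), AT2 (4) at 19.6 ± 6.02% and 13.3 ± 3.24% (exact p = 0.3) and AT2 (3) at 1.44% and 0.678% (exact p = 0.5). AT2 (4) differed by 3.12 points without PPE replicate 1 of experiment 2 and by 3.98 points without the saline library of experiment 1. AT2 (3) differed by 0.0821 points without the saline library of experiment 1 and 1.44 points without that of experiment 2, and by 1.39, 0.477 and 0.412 points without the PPE library of experiment 1 and PPE replicates 1 and 2 of experiment 2. AT2 (3) had a median of 770 UMIs per cell, against 5841 to 6668 in the other substates, and held 116 cells.

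**Figure D3:**
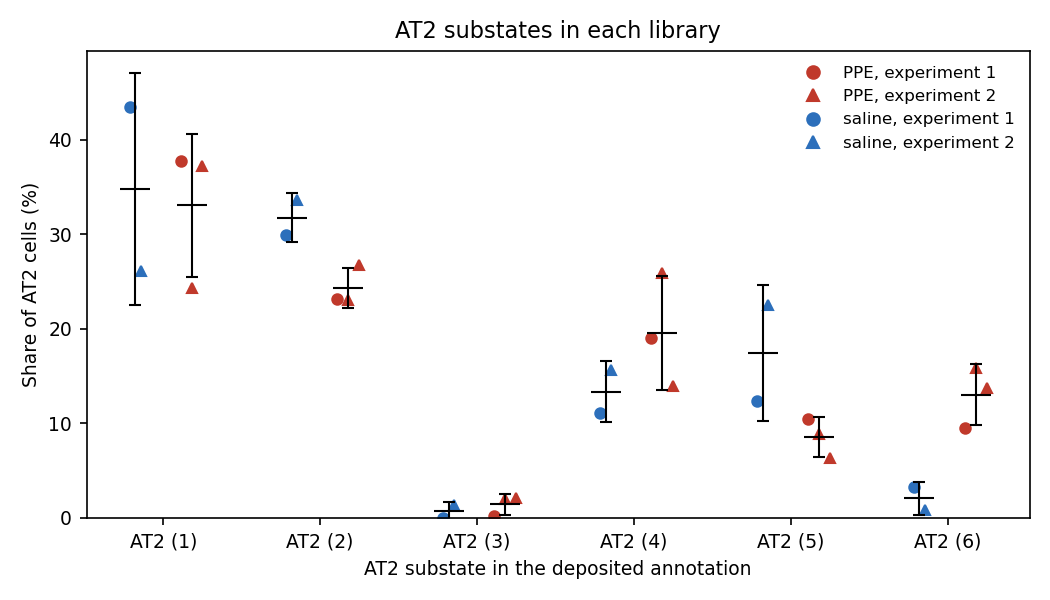
Share of AT2 cells (%) in each deposited AT2 substate; each point is a library, red for PPE and blue for saline, circles for experiment 1 and triangles for experiment 2, and black marks show mean ± SD (n = 3 and n = 2). AT2 (6) lies between 9.50% and 15.9% in PPE libraries and at 0.822% and 3.27% in saline libraries.

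Compared with the other AT2 cells of the same library, the substates differed in the fixed lists, which partly hold genes that defined the clusters and are not independent evidence. AT2 (1) was higher in dissociation stress genes (median log2 0.99, camera adjusted p = 5.27e-71; adjusted p = 0.0108 with an estimated correlation) and AT2 (2) lower in them (−1.07; 0.0120 with an estimated correlation). AT2 (2) was also lower in transitional genes (−0.83; 0.0120) and slightly higher in AT2 identity (0.08; 0.0313). The calls for the remaining substates were lost with an estimated correlation. AT2 (4) was higher in cholesterol synthesis (0.52; adjusted p = 0.0658 with an estimated correlation). AT2 (5) was higher in transitional (1.34) and AT1 genes (0.74), at an adjusted p of 0.0699 each with an estimated correlation. AT2 (6) was higher in NF-kB targets and chemokines (1.45; 0.0788 with an estimated correlation), and AT2 (3) in ciliated markers (3.80; 0.432 with an estimated correlation).

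Within single substates, edgeR with treatment alone called 0 genes in AT2 (1), (2), (4), (5) and (6). With experiment as a term it called 3, 9, 8, 3 and 0 genes. Cyp2b10 was lower in AT2 (1) (−0.83), AT2 (2) (−0.73) and AT2 (4) (adjusted p = 0.000429). Lars2, a mitochondrial leucyl-tRNA synthetase, was higher in the same substates (0.93, 0.79 and 0.72), and Gm42418, whose position overlaps ribosomal RNA sequence, was higher with it in AT2 (4) (0.98, adjusted p = 0.0446). H2-Q7 was higher in AT2 (2) (1.24) and AT2 (5) (1.67), Lyz1 lower in both (−0.67 and −1.19), and Lcn2 higher in AT2 (5) (1.14). Without the saline library of experiment 1 the treatment-only fit called 5 genes in AT2 (5), and without the saline library of experiment 2 it called 3.

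In airway secretory cells, which secrete the airway lining proteins and detoxify inhaled compounds, 6 genes were higher after PPE with experiment as a term. Ccl20, a chemokine for dendritic cells and lymphocytes (chromosome 1, 83116766 to 83119167), stood at 77.9 ± 79.5 against 10.6 ± 5.04 CPM (log2 2.90 ± 0.30, edgeR adjusted p = 7.13e-05). With treatment alone its log2 change was 1.68 without the PPE library and 3.47 without the saline library of experiment 1. Cebpd, an acute phase transcription factor (chromosome 16, 15887286 to 15891031), rose by 0.88 (adjusted p = 0.0201). Cebpd and the other 4, the immunoglobulin transcripts Igkc, Igha, Jchain and Iglc2, were named after their values were seen. Of the secretory cells, 3, all in PPE libraries of experiment 2, carried at least 100 immunoglobulin UMIs. Without them 1 gene passed, Ccl20 (adjusted p = 0.000440), and that alternative was chosen after seeing the data. With treatment alone edgeR called 0 of 11053 genes (53 at an unadjusted p under 0.05) and DESeq2 called Igkc alone. Leaving out the PPE library of experiment 1 gave 4 calls with treatment alone, the immunoglobulin transcripts Igkc, Igha and Jchain and the heat shock gene Hspa1a, which was lower (−4.00).

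The secretory genes with the smallest p did not pass: Dsc2 (1.98), Il4i1 (2.54), Paip2b (0.86) and Cracr2a (0.90) were on the higher side, and Cdh16 (−1.46), Cd59a (−0.72), Lyz1 and Palmd (−0.71) on the lower side. Scgb1a1 (−0.27 ± 1.29), Scgb3a2 (−0.46 ± 0.87), Sftpc (−0.25), Lyz2 (0.29), Krt8 (0.00), Ager (−0.06), Foxj1 (−0.14), Cdkn1a (0.01) and Lcn2 (0.48) did not pass, and Axin2 was at 1.76 against 0.660 CPM. The log2 change of Axin2 was 0.36 without the saline library of experiment 1, 5.98 without that of experiment 2 and 1.58 without the PPE library of experiment 1.

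Of 27 lists, 6 passed camera in secretory cells. NF-kB targets and chemokines rose in 16 of 18 members (median 0.31; Cxcl2 3.77 ± 1.22, Ccl20, Cx3cl1 0.45 and Nfkb2 0.54; adjusted p = 2.48e-05). Surfactant lipid synthesis rose in 14 of 25 (median 0.08; Hacd2 0.48, Fabp5 0.63, Elovl6 0.80 and Acaca 0.44; 0.00166) and cholesterol synthesis in 16 of 24 (median 0.15; Lss 0.58 and Dhcr7 0.63 against Pmvk −0.97; 0.0296). Oxidative phosphorylation fell in 44 of 44 (median −0.30; Ndufa3 −0.35, Atp5g1 −0.31, Ndufs6 −0.31 and Uqcrh −0.42; 2.48e-05). Interferon response fell in 18 of 21 (median −0.22; Isg15 −0.77, Oasl2 −0.75 and Ifi44 −1.03 against Cxcl10 1.62; 0.0301), and antioxidant genes fell in 27 of 35 (median −0.19; Gstp1 −0.96, Cyp2b10 −0.39, Nqo1 −0.63 and Gstm2 −0.23; 0.0422). With an estimated correlation the adjusted p was 0.811 for the lists that rose and 0.850 for those that fell. Adjusted over the list alone 0 members of each passed, and with experiment as a term 4 of NF-kB, 3 of surfactant lipid, 1 of cholesterol, 0 of oxidative phosphorylation, 2 of interferon and 1 of the antioxidant genes.

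With experiment as a term oxidative phosphorylation (0.145) and antioxidant genes (0.0589) no longer passed. Lists that newly passed were AT2 identity (up, 0.00360), MHC class I (up, 0.0204), unfolded protein response (up, 0.00434), AT1 (down, 0.0354), ciliated (down, 5.20e-09), mitochondrial (down, 0.00513) and YAP genes (down, 0.0119), for 11 lists in all. Oxidative phosphorylation had medians of −0.17 in experiment 1 and 0.04 in experiment 2, was lost without PPE replicate 2 of experiment 2 (0.398) and turned upward without the saline library of experiment 1 (0.000131). NF-kB was lost without the PPE library of experiment 1 (0.122) or the saline library of experiment 2 (0.704). Surfactant lipid synthesis was lost without the saline library of experiment 1 (0.132), and cholesterol synthesis without the PPE library of experiment 1 (0.607), PPE replicate 1 (0.0803) or the saline library of experiment 2 (0.921). Interferon was lost without PPE replicate 1 (0.618) or PPE replicate 2 of experiment 2 (0.0866) or the saline library of experiment 1 (0.528), with medians of 0.08 and −0.18 in experiments 1 and 2. Its member Cxcl10 was at 0.0786 without the PPE library and 4.25 without the saline library of experiment 1, and at 0.48 without the saline library of experiment 2. Antioxidant genes changed direction without PPE replicate 2 (0.708) or the saline library of experiment 1 (0.416), with medians of −0.01 and −0.11.

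The other secretory lists gave camera adjusted p-values of 0.0508 for club, 0.0565 for AT2 identity and AT1, 0.0732 for ciliated, mitochondrial and YAP, 0.148 for unfolded protein response and 0.236 for transitional genes. They were 0.252 for sex, 0.286 for proliferation, 0.295 for MHC class I, 0.313 for dissociation stress and extracellular matrix, 0.364 for TGF-beta, 0.719 for Wnt and basal, 0.746 for p53, 0.947 for Notch and primed AT2, and 0.970 for MHC class II and goblet genes. For TGF-beta, Notch, primed AT2 and goblet genes the median, the mean and the test did not share 1 sign.

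In ciliated cells, Lcn2 was higher after PPE with experiment as a term, at 99.8 against 28.5 CPM (log2 1.92 ± 0.18, edgeR adjusted p = 0.000888; chromosome 2, 32384633 to 32388252). With treatment alone its log2 change was 0.95 without the PPE library and 2.44 without the saline library of experiment 1. Surfactant protein transcripts put the share of AT2 RNA in ciliated profiles at 7.13%, 1.93% and 1.80% in the PPE libraries and at 2.86% and 2.09% in the saline libraries. Lars2 and Gm42418, an annotated long non-coding RNA whose position overlaps ribosomal RNA sequence in many mouse data sets, also passed that fit and were named after their values were seen. When experiment 1 was split by sex of cells with experiment and sex as terms, chosen after seeing the data, Lars2 and Gm42418 passed and Lcn2 did not. With treatment alone 0 of 10569 genes passed (69 at an unadjusted p under 0.05), and DESeq2 called 0. The genes with the smallest p were Poglut1 (1.20), Cd177 (1.12 ± 0.30; 117 against 53.9 CPM), Eif3j2 (1.25) and Cxcl5 (2.16) on the higher side. On the lower side they were Isg15 (−1.87 ± 0.49; 7.50 against 26.6 CPM), Lpcat2b (−1.05), Ifit3 (−3.36 ± 0.92) and Ifit1 (−1.02). Without the saline library of experiment 1 Ifit3 was at −1.48, Ifit1 at −0.56 and Cxcl5 at 3.60, and without that of experiment 2 Cxcl5 was at 1.08. The ciliated transcription factor Foxj1 (−0.02), Krt8 (0.04), Cdkn1a (0.21), Sftpc (0.46), Scgb1a1 (0.95), Scgb3a2 (0.30), Lyz2 (0.48) and Ager (0.45) did not pass.

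Of 26 lists 3 passed camera in ciliated cells. Oxidative phosphorylation fell in 44 of 44 members (median −0.26; Ndufb3 −0.28, Atp5j2 −0.33 and Uqcrh −0.34; adjusted p = 1.45e-05) and interferon response in 15 of 18 (median −0.34; Oasl2 −0.92; 0.000347), while AT2 identity markers rose in 17 of 20 (median 0.26; Muc1 0.90, Hc 1.07, Abca3 0.32 and Chil1 0.89; 0.00226). With an estimated correlation the adjusted p was 0.820 for all 3. Adjusted over the list alone 0 members passed in each (0, 4 and 7 with experiment as a term). With experiment as a term oxidative phosphorylation was lost (0.153) and 7 lists passed. Those added were unfolded protein response (0.00126), surfactant lipid synthesis (0.000593), MHC class II (1.25e-05), NF-kB (0.00282) and primed AT2 (0.00126), all upward. MHC class II had a median of 1.68 in experiment 1 and −0.16 in experiment 2, so its rise was seen in experiment 1 alone. The other added lists had positive medians in both experiments. The median of AT2 identity was 1.18 in experiment 1 and −0.11 in experiment 2. In experiment 1 AT2 RNA made up 7.13% of ciliated profiles in the PPE library and 2.86% in the saline library. This share came from 4 surfactant protein genes that are also in the AT2 identity list, so it is not independent of the list. The median of oxidative phosphorylation was −0.17 in experiment 1 and 0.05 in experiment 2. AT2 identity was lost without the saline library of experiment 2 (0.200), where Chil1 was at 0.46, and changed direction without the PPE library of experiment 1 (0.186), where Hc was at 0.13 and Chil1 at 0.0984. Without the saline library of experiment 1 Chil1 was at 1.39. Oxidative phosphorylation was lost without PPE replicate 2 (0.0510) and turned upward without the saline library of experiment 1 (0.000323), without which interferon was lost too (0.534). Without the 2% of cells of each library with the most interferon UMIs, a fit chosen after seeing the data, the interferon list of ciliated cells turned upward and did not pass (0.774, and 0.883 with experiment as a term).

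The other ciliated cell lists did not pass, at camera adjusted p-values of 0.0659 for unfolded protein response and surfactant lipid synthesis, 0.0683 for MHC class II and NF-kB, 0.159 for ciliated markers, 0.260 for transitional and MHC class I, 0.281 for mitochondrial, 0.350 for primed AT2, 0.376 for sex and YAP, 0.433 for extracellular matrix and Notch, and 0.445 for cholesterol genes. They were 0.543 for dissociation stress, 0.603 for TGF-beta, 0.634 for p53, 0.660 for goblet and club, 0.665 for antioxidant and 0.915 for AT1, Wnt and proliferation. For MHC class I, p53, goblet, club, AT1 and Wnt genes the median, the mean and the test did not share 1 sign.

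No cell class passed the test of its share. AT2 cells made up 69.9 ± 3.49% of PPE and 75.7 ± 11.9% of saline cells (exact permutation p = 0.6). By the same exact test ciliated cells were at 13.8 ± 0.379% and 11.6 ± 5.32% (p = 0.7), Club 6.16 ± 2.03% and 5.06 ± 2.58% (p = 0.6), Goblet 3.58 ± 0.763% and 3.04 ± 0.198% (p = 0.4), and Other Activated Club Cells 2.01% and 1.72% (p = 0.9). AT1 cells were 0.435% and 0.437% (exact p = 0.9) and the class named Proliferation 1.40% and 1.02% (exact p = 1). Alveolar macrophages, which an epithelial sort should exclude, were 0.631% and 0.512% (exact p = 0.8). The class named DC was at 2.06% and 0.869% (exact p = 0.5). After adjustment p was 1 for each class, and the design cannot give a p below 0.1.

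Because the series asks about an airway origin of AT2 cells, AT2 cells with an airway transcript were counted after thinning to 2000 UMIs. Scgb1a1 was found in 96.6 ± 4.93% of AT2 cells of PPE libraries and 92.6 ± 10.1% of saline libraries (exact permutation p = 0.7), and Scgb3a2, a second club cell secretoglobin, in 25.1 ± 9.61% and 22.3 ± 11.3% (exact p = 0.8). Ciliated cells, which are not expected to express either, gave 97.8 ± 3.41% and 96.2 ± 5.33% for Scgb1a1 and 32.6 ± 9.19% and 31.4 ± 8.58% for Scgb3a2. The mean AT2 shares are below those of ciliated cells, so they do not measure an airway origin. Background of free RNA could give such shares in both, which was not tested. Within experiments the PPE minus saline differences in AT2 cells were 5.48 and −0.262 points for Scgb1a1 and −0.395 and 0.309 points for Scgb3a2. Thinning left out 0, 50 and 79 AT2 cells of the PPE libraries and 0 and 55 of the saline libraries. Without thinning Scgb1a1 was found in 99.8% to 100% of AT2 cells and 99.3% to 100% of ciliated cells of each library. Scgb3a2 was then found in 69.7%, 63.8% and 52.1% of AT2 cells in the PPE libraries and 59.4% and 61.4% in the saline libraries, and in 77.3%, 61.2% and 54.1% against 66.4% and 65.9% of ciliated cells. Median depth was 5065 UMIs for ciliated cells, while the AT2 medians per library were 17342, 5705.5 and 4212 for PPE and 13453 and 5652 for saline.

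Whether PPE acted differently on AT2 and secretory cells was tested as an interaction. edgeR called 0 of 12519 genes (199 at an unadjusted p under 0.05). It called 13 when experiment by class was added as a term after seeing the data, all with the larger PPE effect in AT2 cells. Among the lists 7 of 28 differed between the classes in camera, led by interferon response, whose PPE effect was larger in AT2 than in secretory cells (22 of 24 members on the AT2 side, median difference 0.65, adjusted p = 5.52e-10; adjusted p = 0.231 with an estimated correlation). Leaving out the PPE library of experiment 1 gave 10 genes and 13 lists, and leaving out the saline library of experiment 2 gave 12 lists.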

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

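The PPE effects in AT2 and airway secretory cells were compared by tests of the difference itself. The test of each gene with the library as a block was chosen before the data were examined. The list tests of this difference, the fit with experiment by class as a term and the tests of explanations below, apart from the fit with experiment as a term, were chosen after the results were seen.

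The PPE effect on 7 lists differed between the cell types in camera. Interferon response lay on the AT2 side in 22 of 24 members (median difference 0.65, adjusted p = 5.52e-10; adjusted p = 0.231 with an estimated correlation). Oxidative phosphorylation did so in 44 of 44 (0.16, adjusted p = 5.69e-08; 0.887 with an estimated correlation) and MHC class I in 16 of 16 (0.36, adjusted p = 2.34e-06; 0.887). Primed AT2 and acute phase genes did so in 13 of 17 (0.48, adjusted p = 5.23e-05; 0.571 with an estimated correlation) and ciliated markers in 17 of 19 (0.43, adjusted p = 0.00109; 0.887). NF-kB and chemokines did so in 13 of 21 (0.13, adjusted p = 0.0324; 0.887 with an estimated correlation). AT2 identity lay on the secretory side in 14 of 20 (−0.14, adjusted p = 0.0413; 0.887). With experiment by class as a term 14 lists differed, among them signs of handling, RNA quality and other cells. Mitochondrial transcripts (adjusted p = 0.00319) and club markers (0.0492) were added on the AT2 side. Dissociation stress (0.00200), transitional genes (0.0207), unfolded protein response (0.0285), and surfactant lipid synthesis and macrophage markers (0.0492 each) were added on the secretory side.

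With experiment by class as a term, 13 genes had a larger PPE effect in AT2 cells, against 0 without it. Those named here were named after their values were seen. The log2 differences were 2.18 for Isg15, 1.90 for Itm2a, 1.75 for Cxcl5, 1.70 for AW112010, 1.67 for Pigr and 1.38 for Cxcl1. They were 1.18 for Slc1a1, 1.14 for Cd14, 1.07 for Ifitm3, 0.89 for Ly6a and 0.87 for Cp, and Steap4 passed at an adjusted p of 0.00315. The adjusted p ran from 0.000342 (Cd14) to 0.0475 (Pigr). Cd14, Steap4, Cxcl1 and Cxcl5 are among the leading genes of AT2 (6), whose share was larger in PPE libraries. With experiment as a term and AT2 (6) cells left out, their PPE effects in AT2 cells were smaller. They went from 1.59 to 0.78, 1.69 to 0.57, 1.65 to 0.70 and 2.93 to 1.76. Because these genes lead AT2 (6), leaving out its cells was bound to lower these effects, whatever their cause. The difference between the classes was not tested without AT2 (6) cells.

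The larger share of AT2 (6) in PPE libraries was weighed first. An unequal mix of the 2 experiments is argued against by the fit with experiment as a term (adjusted p = 0.00586) and by the higher share in PPE libraries of both experiments. Depth as the whole cause is argued against by experiment 2, where by the median UMIs of AT2 cells 1 PPE library was close to the saline library (5705.5 against 5652) and 1 shallower (4212), and the lower of their shares still lay 12.9 points above that of the saline library. A rise of the defining genes in all AT2 cells, which would carry more cells over the border of the substate, cannot be told apart. The 10 leading genes of AT2 (6) were higher in PPE cells outside it (median log2 0.78), and 0 of them passed there. Most AT2 (6) cells came from PPE libraries, so the choice of these genes can itself favour genes higher in PPE cells. Elastase treatment, the difference the design names, stays open as a cause.

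By camera interferon response genes were higher in AT2 cells and lower in airway cells of PPE libraries, although in secretory cells the median was 0.08 in experiment 1 and −0.18 in experiment 2 and the call was lost without PPE replicate 1 (adjusted p = 0.618) or 2 (0.0866) of experiment 2 or the saline library of experiment 1 (0.528). In AT2 cells the call stayed without the 2% of cells of each library with the most interferon UMIs (adjusted p = 1.34e-12) and without AT2 (6) (adjusted p = 7.59e-08), which argues against either as the whole cause; with all cells its adjusted p was 0.251 with an estimated correlation and 0.406 in fry. In ciliated cells the camera call ended without such cells (adjusted p = 0.774). The mean change went from −0.53 ± 0.85 (SD over members) to 0.01 ± 0.43 and the median from −0.34 to −0.02, so a few cells may account for it. In the saline library of experiment 1, 3 of 146 ciliated cells held 26.9% of the interferon UMIs. In secretory cells the camera call also ended (adjusted p = 0.292). The mean there only went from −0.18 ± 0.65 to −0.11 ± 0.72 and the median stayed at −0.22, so a few cells cannot be told apart from a difference in many. An effect of elastase on interferon genes of AT2 cells stays a hypothesis.

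Lcn2 was higher in ciliated cells of PPE libraries, and RNA of AT2 cells, where Lcn2 is abundant, may account for most of it. From the AT2 level and 4 surfactant protein genes, chosen after the Sftpc ratios were seen, the expected Lcn2 was 80.8%, 84.2% and 90.0% of that observed in the PPE libraries and 99.5% and 76.2% in the saline libraries. The difference between the groups was 1.64 on the log2 scale in the observed levels and 1.60 in the expected levels. A smaller rise within ciliated cells after elastase stays open.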

How the results depend on the processing

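The settings chosen after the data were seen were experiment 2 alone, the split of experiment 1 by sex of cells, and the fits without the cells of highest doublet score, AT2 (6), AT2 (3), immunoglobulin-high or interferon-high cells, or experiment 2 cells of the other sex. Blocked list tests by an estimated correlation or fry, the term of experiment by class, and all list tests in ciliated cells and of the difference between classes were also chosen then. Without an experiment term edgeR called 0 genes on all 5 libraries, so the counts of genes depend on that term, read as a block, and on the tool. In simulated counts that fit recovered 2-fold changes in 32% of cases in AT2 cells, 0% in secretory cells and 1% in ciliated cells. With the block at the same depth the shares were 99%, 99% and 96%. The simulation used means of each experiment and a spread estimated with the block, so it favoured the block by construction. It cannot decide which fit suits the measured data. Measured genes can fall short of these shares: Lcn2 in AT2 cells did not pass with the block, at a log2 change of 1.36. Depth limits which genes can be tested: the low-count filter left 12084 in AT2, 11053 in secretory and 10569 in ciliated cells. In this part a value beside a gene is a log2 change, and a value beside a list is an adjusted p. Where a left-out library leaves 1 saline library, that library is assumed to vary like the PPE libraries. Of 1851 single values under settings that kept every library, or used experiment 2 alone, 49 changed direction, 122 passed only there and 76 passed only in the reported fit. Of 779 single values with 1 library left out, 76 changed direction, 21 passed only there and 21 passed only in the reported fit. The rest of both kept their direction and side of the threshold. Apart from leaving out a library and what is stated below, the cause was not tested.

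With experiment as a block, edgeR called 6 genes in AT2, 6 in secretory and 3 in ciliated cells, and 3, 9, 8 and 3 in AT2 (1), (2), (4) and (5). The block gave 11 secretory and 7 ciliated lists and an AT2 oxidative phosphorylation list at adjusted p = 0.000978. The log2 change was 0.0633 for Lyz2 in AT2 cells and 0.000524 for Ager in secretory cells, and neither passed. On cell counts it called 1 substate, AT2 (6), as it did without the experiment 2 cells of the other sex (1), and gave log2 changes of −0.11 for alveolar macrophages, −0.19 for Other Activated Club Cells and −0.71 for Proliferation. It changed no other call beyond those given in the report. A block of experiment and replicate number leaves PPE replicate 1 of experiment 2 without a saline partner and 1 residual degree of freedom. False calls made up 13.1%, 6.70% and 9.13% of its calls in simulated counts of AT2, secretory and ciliated cells. With experiment and replicate number as the block, 77, 42 and 11 genes passed. The log2 change of Lyz2 was then 0.0257 in AT2 cells, with Krt8 at −0.00372 and Ager at 0.00434 in secretory cells and Foxj1 at 0.00165 in ciliated cells, none of which passed. With experiment by class as a term 13 genes and 14 lists differed between the classes.

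DESeq2 called 16 AT2 genes and 1 secretory gene. Without AT2 (6) the blocked fit called 1 gene, Thbs1 (log2 −1.06, adjusted p = 0.0310). The adjusted p of oxidative phosphorylation was 0.0249 there, and the log2 change of Lyz2, which did not pass, was 0.0356. Without AT2 (3) the blocked fit called 6 genes, with a log2 change of 0.0644 for Lyz2, and without the block that of Foxj1 was −0.0396. Without the 3 immunoglobulin-high cells the blocked fit called 1 secretory gene, Ccl20, with a log2 change of 0.00313 for Ager. Without AT2 (6) the log2 change of Cd14 was 0.78 ± 0.11 in place of 1.59, that of Cxcl2 0.95 ± 0.58 in place of 2.03, that of Steap4 0.57 ± 0.20 in place of 1.69 and that of Cyp2b10 −0.74 ± 0.10 in place of −0.80. These 4 did not pass, and Il4i1 was no longer among the genes tested. As leading genes of AT2 (6), Cd14, Cxcl2 and Steap4 were bound to fall when its cells were left out.

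Experiment 2 alone, which has 1 saline library, called 123 AT2, 82 secretory and 75 ciliated genes. The log2 change in AT2 cells was 0.0529 for Lyz2 and −0.45 for Foxj1. In secretory cells Atp5g1 was at 0.0406, Ndufs6 at 0.0541, Uqcrh at 0.0818, Sftpc at 0.0530, Scgb1a1 at 0.22 and Scgb3a2 at 0.18. Lyz2 was at −0.0136, Krt8 at −0.23, Ager at 0.0356 and Cdkn1a at −0.17 there. In ciliated cells Ndufb3 was at 0.0535, Sftpc at −0.63, Lyz2 at −0.000772, Krt8 at −0.11 and Ager at −0.61. The split by sex had experiment and sex as terms. It called no gene in AT2 cells, so the genes called there with experiment as a term were lost. In secretory cells it called 1 gene, Ccl20 (2.98, adjusted p = 0.0152). In ciliated cells it called 2 genes, Lars2 (0.83, adjusted p = 0.0236) and Gm42418 (1.09, adjusted p = 6.49e-05), and Lcn2 did not pass. Cells of each sex from an experiment 1 library entered as separate columns, so these adjusted p-values count parts of a library as libraries. The split gave log2 changes of Lyz2 0.0511 and Ager 0.0580 in AT2 cells and Sftpc 0.0873 and Ager 0.13 in secretory cells.

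An estimated correlation left 0 lists in AT2, secretory and ciliated cells and 0 for the difference between classes, and so did fry. Both with the block left 0, with AT2 oxidative phosphorylation at adjusted p = 0.703 and 0.589. In simulated counts of AT2 and secretory cells neither recovered a list shifted on purpose, so these losses cannot decide whether a list shifted. In substates an estimated correlation left 1 list in AT2 (1) and 0 in AT2 (3), (4), (5) and (6), and AT2 (5) had 8 lists without the library as a block. Without the interferon-high cells the interferon list of ciliated cells had an adjusted p of 0.774, and 0.883 with the block. Both are upward, and with the block 13 secretory and 8 ciliated lists passed, with AT2 oxidative phosphorylation at 0.00111. Without a low-count filter 5 ciliated lists passed. Without the cells of highest doublet score the AT1 share differed by 0.00276 points, the log2 change of Foxj1 was −0.0241 in AT2 and 0.0453 in secretory cells, and Ager was at 0.0636 in secretory cells. Without the Scrublet calls the log2 change of Foxj1 was −0.0158 in AT2 cells. With equal cell numbers that of Lyz2 was −0.41, Foxj1 at 0.0605 and Cdkn1a at −0.0689 in secretory cells.

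Leaving out each library in turn gave these ranges. Gene counts ran from 0 to 4 in AT2 and in secretory cells and from 0 to 10 for the difference between classes. They ran from 0 to 1 in AT2 (1), (2), (4) and (6) and from 0 to 5 in AT2 (5). The single call came without the PPE library of experiment 1 in AT2 (1), (2) and (4) and without the saline library of experiment 1 in AT2 (6). Lists numbered 6 to 10 in secretory cells, 5 to 8 in ciliated cells and 5 to 13 for the difference. The most secretory lists, 10, came without the PPE library of experiment 1. Without the PPE library of experiment 1 the ciliated lists numbered 5, without PPE replicate 1 of experiment 2 they numbered 7, without PPE replicate 2 they numbered 8, and without either saline library 6.

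Over the same fits, the adjusted p of AT2 oxidative phosphorylation ran from 1.60e-07 to 0.832. In secretory cells MHC class I ran from 0.000490 to 0.867, YAP from 0.0144 to 0.921, antioxidant from 7.41e-05 to 0.708 and ciliated markers from 7.83e-06 to 0.704. Mitochondrial transcripts ran from 0.0482 to 0.752, oxidative phosphorylation from 1.40e-13 to 0.398 and unfolded protein response from 0.0106 to 0.925 there. In ciliated cells AT2 identity ran from 1.53e-06 to 0.200, MHC class II from 0.000145 to 0.555, oxidative phosphorylation from 3.91e-14 to 0.0510 and primed AT2 from 0.000729 to 0.849. Each of these lists had a fit with the opposite direction.

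Log2 ranges in AT2 cells were −0.26 to 0.0155 for Ager, −0.29 to 0.10 for Axin2, −0.84 to 2.54 for Foxj1 and −0.23 to 0.23 for Lyz2. They were −0.13 to 0.95 for Scgb1a1, −0.14 to 0.80 for Scgb3a2 and −0.71 to 0.32 for Sftpc. In secretory cells they were −0.25 to 0.15 for Ager, −0.73 to 0.29 for Atp5g1, −0.13 to 0.12 for Cdkn1a, −0.69 to 0.79 for Foxj1 and −0.46 to 0.0496 for Gstm2. They were −1.55 to 0.0283 for Gstp1, −0.13 to 0.12 for Krt8, −0.21 to 1.89 for Lcn2, −0.73 to 0.18 for Ndufa3 and −0.76 to 0.35 for Ndufs6. For Scgb1a1 they were −0.75 to 0.46, for Scgb3a2 −1.07 to 0.64, for Sftpc −0.58 to 0.19 and for Uqcrh −1.01 to 0.61. In ciliated cells they were −0.67 to 0.80 for Ager, −0.78 to 0.33 for Atp5j2, −0.14 to 0.11 for Foxj1, −0.13 to 0.23 for Krt8 and −0.61 to 1.08 for Lyz2. For Ndufb3 they were −0.70 to 0.29, for Ndufs6 −0.66 to 0.18, for Scgb3a2 −0.17 to 0.83, for Sftpc −1.54 to 1.37 and for Uqcrh −0.79 to 0.31. Other printed genes kept their direction wherever they were tested, but many moved widely. Examples in AT2 cells were Ciita (0.18 to 0.93), H2-DMb2 (0.73 to 1.83), H2-Ab1 (0.0764 to 0.25) and Cxcl3 (1.22 to 2.26). So were Mvd (0.11 to 0.71), Lss (0.0782 to 0.34) and Pmvk (−1.53 to −0.68). Examples in secretory cells were Axin2 (0.36 to 5.98), Lyz1 (−3.35 to −0.86), Cxcl10 (0.0786 to 4.25), Ccl20 (1.68 to 3.47) and Nqo1 (−0.96 to −0.25). Examples in ciliated cells were Ifit3 (−4.27 to −1.48), Ifit1 (−1.43 to −0.56), Cxcl5 (1.08 to 3.60), Hc (0.13 to 1.40), Chil1 (0.0984 to 1.39) and Scgb1a1 (0.32 to 1.79).

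Differences in share, in points, ran from −10.4 to 6.96 for AT2 (1), 0.0821 to 1.44 for AT2 (3), 3.12 to 9.12 for AT2 (4), −14.2 to 2.60 for AT2 cells, −1.59 to 5.94 for ciliated and −0.728 to 2.92 for Club. They ran from −0.896 to 1.47 for Other Activated Club Cells, −0.790 to 0.989 for Proliferation, −0.392 to 0.631 for alveolar macrophages and −0.0243 to 0.0204 for AT1. For AT2 cells with Scgb1a1 they ran from −3.11 to 11.2 and with Scgb3a2 from −5.24 to 10.7. Scgb1a1 turned negative without the saline library of experiment 1, and Scgb3a2 without that library or either PPE library of experiment 2.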

Other observations

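The prediction of AT2 (6) membership below was chosen after the results were seen, and the list tests between substates were chosen before. AT2 (6) cells, compared with the other AT2 cells of their library, were higher in the immune lists beyond chemokines. Interferon response (median log2 0.83), primed AT2 and acute phase genes (0.82), MHC class I (0.67) and MHC class II (0.44) lay higher and cholesterol synthesis (−0.26) lower. All 5 passed camera, and the adjusted p with an estimated correlation was 0.0788 for each. AT2 (5) lay lower in cholesterol synthesis (−0.57), surfactant lipid synthesis (−0.41) and AT2 identity (−0.23), at an adjusted p of 0.0699 each with an estimated correlation. AT2 (2) lay lower in primed AT2 and acute phase genes (−0.87) and in NF-kB targets and chemokines (−0.62), at an adjusted p of 0.0182 each with an estimated correlation.

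Within substates, other genes also passed between PPE and saline with experiment as a term and were named after their values were seen. In AT2 (2) Ly6i was higher (1.74), as was the stress-response factor Atf5 (1.17), and Pon1 (−0.89) and Slc38a4 (−0.77) were lower. In AT2 (4) Adamts15 (0.97), Slpi (0.85) and the immunoglobulin transcript Igkc were higher, and Prmt8 (−0.75) and Acot2 (−0.70) were lower. All 8 cells with at least 100 immunoglobulin UMIs were in PPE libraries of experiment 2, and 0 of them were AT2 cells.

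The matrix holds features named for 2 reporter genes. Both names refer to SV40 sequence, and whether reads of one were counted for the other was not tested. A green fluorescent protein transcript, egfp-sv40, was found in 66.7% and 66.7% of alveolar macrophages of the PPE libraries of experiment 2 and in 89.2% of its saline library, and the tdTomato transcript, tdtomato-sv40, in 0%, 6.06% and 0%. At least 3 such green UMIs were found in 2.77%, 2.65% and 5.71% of AT2 cells of the PPE libraries and in 2.25% and 4.44% of the saline libraries. In those AT2 cells tdTomato stood at 13.2, 24.6 and 4.01 CPM in the PPE libraries and 7.98 and 1.57 CPM in the saline libraries. In AT2 cells without the green transcript it stood at 45.4, 36.9 and 28.9 CPM and at 26.6 and 32.9 CPM.

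The PPE library of experiment 1 held 1516 cells with Xist and no Y-linked transcript and 552 with the reverse, and its saline partner 1070 and 552. In experiment 2 PPE replicate 1 held 1298 cells with Y-linked transcripts alone, while PPE replicate 2 and the saline library held 2687 and 3417 with Xist alone. Of the 20 AT2 (6) cells in that saline library, 8 carried Y-linked transcripts without Xist, against 12 in the whole library. Without the cells of the other sex AT2 (6) made up 0.495% of that library's AT2 cells, against 0.822% with them. Cells of the class named Proliferation numbered 86 in the PPE library of experiment 1 and 56 in the saline library of experiment 2, and 5 to 9 in the other libraries. Pmvk stood at 253, 187 and 165 CPM in AT2 cells of the PPE libraries and at 288 and 657 CPM in the saline libraries. Gm42418 stood at 51424, 22792 and 17162 CPM in the PPE libraries and at 14188 and 16609 CPM in the saline libraries.

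Membership of AT2 (6) was also predicted in each experiment by a classifier trained in the other. The predicted share was 9.91% against 3.92% in experiment 1, and 7.64% and 9.18% against 0.534% in experiment 2. With the 200 leading genes left out it was 7.67% against 3.02%, and 1.52% and 1.64% against 0.329%. With 500 left out it was 7.96% against 3.53%, and 1.25% and 1.14% against 0.452%. The area under the curve was then 0.603 to 0.701, so the classifier recovered the deposited substate poorly. Because a classifier can learn the treatment itself, these shares do not separate a larger substate from a shift of all AT2 cells, for which the median log2 change outside AT2 (6) was 0.78.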
